A study of Mus musculus with 12 samples.

How the data were processed

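Total RNA of cells sorted as HSCs from mouse femur marrow was assayed in 12 libraries, 3 for each of the groups wild-type sham, wild-type ICH, Adrb3-/- sham and Adrb3-/- ICH, per the labels' protocols. The design text gives 6 mice of each genotype for the 12 samples, so each library was taken as 1 mouse. The instrument, the panel, the scaling method and any threshold are not given in the sources used here.

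The deposited signal values formed a single table with 754 genes, 8 negative control probes and 6 positive control probes. From the values, each gene's signal is a whole number of counts multiplied by 1 factor per library: all values up to 1000 counts were whole within 0.006. Genes with under 20 counts carry the value 20, which was not scaled. The control probes are unscaled counts. The geometric mean of the 20 reference genes was 437 in 11 libraries and 205 in wild-type sham replicate 1, where 6 reference genes were under 20 counts. In Adrb3-/- ICH replicate 2 there were 243 genes under 20 counts, and 20 counts equal a value of 103, so a value of 20 there means a level under 103. Because the values at 20 cannot be turned back into counts, no count model was used, and the deposited values were not scaled again. Molecules were counted once per library, so the precision of a level is set by its counts and by the spread between mice. No pair of libraries of a group came close to being duplicates (chi-square divided by its degrees of freedom of at least 7.34). Of the 754 symbols, 744 are current and 9 are older names in the gene table of GRCm38.p6, which was used for names only and 1 is neither.

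Genes were kept when their mean over the 12 libraries exceeded the background, taken as the mean plus 2 SD of the negative controls. Since the controls are unscaled, this was computed in each library, multiplied by the library's factor and averaged, which gave 106 and kept 593 genes, with 161 removed. That reading of the rule was worked out after the table was seen. The kept set rests in part on wild-type sham replicate 1, where 1 count was worth 15.5, which raised the background and many means. Over the other 11 libraries only 478 genes had a mean above that background. Among the named genes, Hpgds (mean 73.3 over those 11, and 465 in that library), Cxcr1 (74.6) and Gzma (61.2) were kept only through it. Each passed the filter recomputed over the 11, which kept 674 genes. A linear model with 4 group means was fitted to log2(value + 1) with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 7 two-sided contrasts: ICH against sham in each genotype, Adrb3-/- against wild type in each treatment, their interaction, and both averages. All groups share 1 estimate of the spread, with 8 residual degrees of freedom. Adjusted p is by Benjamini-Hochberg over the 593 genes of a contrast, with a threshold of 0.05. The added 1 shrinks the changes of low genes slightly. The unscaled 20 can distort them more, in either direction. With its value at 20 set to the worth of 20 counts, the change of Hpgds for ICH in Adrb3-/- went from -2.03 to -1.26 with 11 libraries.

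Of 35 gene lists fixed before the data were examined, the 25 with at least 5 kept genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists of a contrast. Camera with a correlation estimated from the residuals and the rotation test fry were the alternatives. No list call held with an estimated correlation in any comparison, with 12 or 11 libraries. Fry's test of a shift to one side, which does not compare a list with other genes, gave 0 lists in 13 of these 14 cases and 1 in the average over treatments with 11 libraries (cell cycle genes, adjusted p = 0.0377). Its test of change in either direction gave 3 lists for ICH against sham in Adrb3-/- mice with 11 libraries: monocyte, macrophage and dendritic cell markers (adjusted p = 0.00482), chemokine receptor genes (0.00801) and complement and Fc receptor genes (0.0391). It gave 0 in the other 13 cases. The 10 lists with too few kept genes included erythroid and megakaryocyte genes (4 kept), cyclin-dependent kinase inhibitor and p53 target genes (3), adrenergic and cAMP signalling genes (1), PI3K, Akt and mTOR genes (2), Notch genes (1), DNA repair genes (2), chromatin and transcription regulator genes (4), B cell markers (2), and NK cell and cytotoxic markers (3).

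The test was checked on simulated data with 200 of 593 genes changed, in 20 draws. For ICH against sham in Adrb3-/- mice with 11 libraries, 58.5% of genes changed by 1 on the log2 scale and 95.4% of those changed by 2 were recovered, and 3.51% of calls were false. The simulation with 12 libraries treats all 12 as sound and recovered 57.6% and 94.5%. The draws used independent noise, with no values held at 20. With few changed genes the adjusted threshold is harder to pass, and such draws were not run. The recovered shares are therefore not the power of the real comparisons. A list shifted by 1, mature neutrophil markers, was recovered in 20 of 20 draws, with 2 other lists called over all draws. In the real libraries these markers went up and down together within groups (mean correlation of residuals 0.755). Recovery under such correlation between genes was not tested. The draws therefore cannot show how reliable camera with a preset correlation is for these lists.

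The genes named were chosen by a rule fixed at the same time as the lists: the 10 with the largest change in each direction among those past the threshold (5 for the interaction), filled to 5 per direction by the smallest unadjusted p and then given as values. It added the 3 members of smallest p of each list past its threshold and a fixed set of genes. The rule was applied to the fit with 12 libraries and, after the failed library had been seen, to the fit with 11. Of the 206 pairs of gene and comparison it gave, 20 differed in sign between the fits, 0 of them in the 2 comparisons without wild-type sham libraries. The text prints the change of 68 pairs.

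Leaving out each library in turn was planned, and the fit without wild-type sham replicate 1 is one of these. The other settings chosen in advance were no filter, a stricter filter (377 genes), pseudocounts of 0.5 and 10, median centring, centring on reference genes, quantile normalization, a fit of the compared groups alone, the replicate number as a block, array weights, a mean-variance trend with a robust prior, and looser thresholds. Alternatives chosen after seeing the data start from the 11 libraries: leaving aside each further library, the filter recomputed (674 genes), a common floor that raises every value to at least 103 (557 genes above it in 3 or more libraries), each value at 20 set to the worth of 20 counts in its library with the other values as deposited, both scalings, the block, both other list tests and looser thresholds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.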

Results

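The transcripts of 754 genes were measured in total RNA of cells that had been sorted as HSCs by flow cytometry from the femur marrow of male mice, 3 days after ICH or sham surgery. Wild-type mice of the C57/BL6 strain were compared with Adrb3-/- mice, in which the gene of the beta-3 adrenergic receptor is inactivated. The title of the study asks what innervation through this receptor does to marrow cells. The design held 6 wild-type and 6 Adrb3-/- mice, in 4 groups of 3 libraries. Adrb3 itself was not analysed here, so the genotype could not be checked on the targeted gene, and Adrb1, Cdc42, Ly6a, Spi1, Ly6c2, Il7r, Mki67 and Cdk6 were likewise not analysed here. In the 11 libraries other than wild-type sham replicate 1, the highest mean values belonged to S100a9 (150064) and S100a8 (145284), the calprotectin subunits that neutrophils hold in large amounts, and to Camp (28692), an antimicrobial granule peptide. Mpo, the myeloperoxidase of myeloid granules, averaged 8175. Kit, the stem cell factor receptor, averaged 167 and ranked 338 of 754 genes, and Cd34, a surface marker of progenitors, averaged 830. Of these, all but Kit were chosen after their values were seen. The measured genes fixed in advance for their role in stem or progenitor cells (Kit, Cebpa, Gata2, Nr4a1, Ly6c1 and Flt3) passed the test in none of the 7 comparisons, with a smallest unadjusted p of 0.109 for Flt3 averaged over treatments.

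The libraries differed in quality. In 11 of them, genes with at least 20 counts summed to between 110740 (Adrb3-/- ICH replicate 2) and 556407 counts (wild-type sham replicate 3). The strongest positive control, POS_A, gave between 6278 (Adrb3-/- ICH replicate 1) and 44207 counts in these 11. In Adrb3-/- ICH replicate 1, POS_A was 19.8% of the median of the 11. The control POS_E gave 21 counts there, under the highest negative control (61), and 104 genes were under 20 counts. Its array weight was 0.251, the lowest after wild-type sham replicate 1, and it was kept. In wild-type sham replicate 1 the genes summed to 24775 counts, POS_A gave 79 counts, or 2.94 times the mean of that library's negative controls, and 1 count was scaled to a value of 15.5. Its values correlated with those of the other libraries at r between 0.0902 and 0.169 across genes, while the other 11 correlated among themselves at 0.838 or higher. S100a8 and S100a9 together took 1.32% of its counts (95% Wilson interval 1.18 to 1.47%), 23.2% in Adrb3-/- sham replicate 3 (23.1 to 23.4%) and between 43.9% and 55.3% in the other 10 libraries. These intervals cover counting error alone. Every comparison below was therefore given both with 12 libraries, as planned, and with the 11 libraries left without wild-type sham replicate 1, where the wild-type sham group has 2 libraries.

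**Figure D1:**
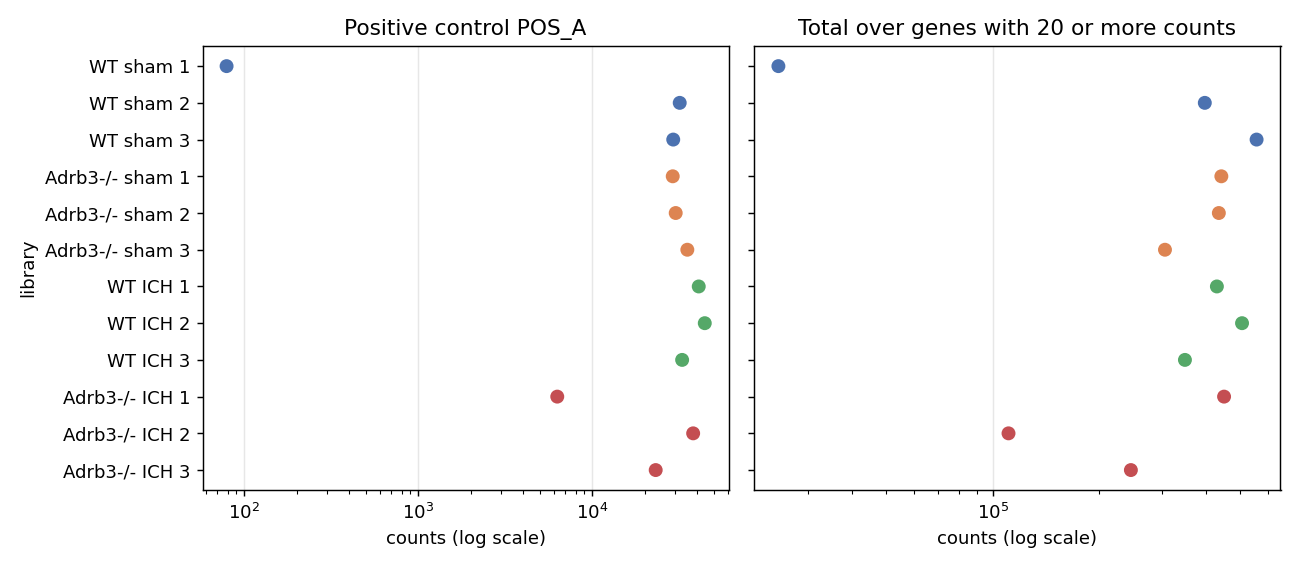
Counts of the positive control POS_A (left) and total counts over genes with 20 or more counts (right) in each of the 12 libraries, on log axes, with 1 point per library coloured by group. Wild-type sham replicate 1 stands at 79 POS_A counts and 24775 gene counts, below the other 11 libraries on both axes.

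The comparison of ICH with sham in Adrb3-/- mice asks how the sorted cells differed after ICH when the receptor was missing. With 11 libraries 4 genes were lower after ICH, of which 1 (Mrc1) is in the fixed list of monocyte, macrophage and dendritic cell markers, 1 (Vcam1) in that of stromal and endothelial cell markers, and Apoe and Hpgds in none. Mrc1, the mannose receptor of macrophages, fell from 902 ± 343 to 153 ± 49.0 (SD, n = 3 each), a log2 change of -2.54 (SE 0.37). Apoe, a lipid carrier that macrophages secrete, fell from 2053 ± 660 to 599 ± 116, a log2 change of -1.74 (SE 0.26). Vcam1, an adhesion molecule of stromal cells and marrow macrophages, fell from 1099 ± 464 to 187 ± 92.0, a log2 change of -2.61 (SE 0.48), and Hpgds, a prostaglandin D synthase, fell from 146 ± 29.5 to 37.0 ± 14.9, a log2 change of -2.03 (SE 0.36). These were the 4 genes, of 593 tested, that passed with 11 libraries (limma, adjusted p = 0.0175 for Mrc1 and Apoe and 0.0462 for Vcam1 and Hpgds). With 12 libraries none passed, at adjusted p = 0.68 for Mrc1, 0.103 for Apoe and Vcam1, and 0.988 for Hpgds, with the same changes and larger errors (SE 0.83 for Mrc1). At an unadjusted p under 0.05 there were 22 genes with 12 libraries and 48 with 11, where chance gives 29.6 if no gene changed, and the median change of all genes was -0.11.

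Among the fixed lists, mature neutrophil markers rose in Adrb3-/- ICH libraries, with 13 of 13 members positive and a median log2 change of 0.75 (camera with a preset correlation, adjusted p = 8.00e-08 with 11 libraries and 1.97e-07 with 12). Adjusted p was 0.683 and 0.353 with an estimated correlation. None of the 13 passed alone, whether adjusted over all genes or adjusted over the list alone. Examples were Cxcr2, the chemokine receptor of neutrophils, at 0.95 (SE 0.40), and Csf3r, the granulocyte colony-stimulating factor receptor, at 0.83 (SE 0.30). S100a8 and S100a9, members of this list, took 23.2% of the counts in Adrb3-/- sham replicate 3 and at least 44.3% in the other 5 Adrb3-/- libraries. MHC class II genes fell, with 12 of 12 members negative and a median of -0.68 (adjusted p = 0.00199 with 11 libraries, 0.683 with an estimated correlation; 0.00507 and 0.486 with 12). The antigen-presenting chain genes H2-Eb1 and H2-Ab1 both stood at -0.99 and the costimulatory ligand Cd86 at -0.74, and 1 member passed when adjusted over the list alone and 0 over all genes. Monocyte, macrophage and dendritic cell markers fell, with 13 of 18 members negative and a median of -0.42 (adjusted p = 0.0157 with 11 libraries, 0.683 with an estimated correlation; 0.00336 and 0.353 with 12). With 11 libraries 6 of its members were lower adjusted over the list alone and 1, Mrc1, over all genes, and with 12 libraries 5 and 0. Among the 6, Adgre1, which encodes the F4/80 antigen, stood at -1.65 (adjusted p = 0.0543) and the haemoglobin scavenger receptor Cd163 at -2.14 (0.0593). With values at 20 set to the worth of 20 counts, a setting chosen after the data were seen, their changes stayed the same. Both then passed over all genes (limma, adjusted p = 0.0369 for each). Stromal and endothelial cell markers were negative in 10 of 11 members (adjusted p = 0.452) and mast cell, basophil and eosinophil markers in 8 of 10 (0.681), and neither list passed. Outside the lists, C1qc, a complement component made by macrophages, stood at -2.77 (adjusted p = 0.0814 with 11 libraries and 0.196 with 12). The kinase gene Mapk13, of the list of Ras and MAP kinase genes, which did not pass, stood at 0.93 (0.392 with 11 libraries).

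The 4 gene calls rest on few libraries. With 11 libraries as the start, 0 genes passed without Adrb3-/- sham replicate 2 or 3, Adrb3-/- ICH replicate 3 or wild-type ICH replicate 2. There were 2 without Adrb3-/- sham replicate 1 or wild-type ICH replicate 1 or 3, and 16 without Adrb3-/- ICH replicate 1. Wild-type libraries enter this comparison only through the shared estimate of the spread. Leaving one aside moves the errors and degrees of freedom, and not the changes. A fit of the Adrb3-/- libraries alone gave adjusted p = 0.211 for all 4. Hpgds was under 20 counts in Adrb3-/- ICH replicate 2, where the level is only known to lie under 103, and with that value at 103 its change was -1.26 (SE 0.35) and the call ended (adjusted p = 0.165). Under the same setting for all values at 20, the calls for Mrc1, Apoe and Vcam1 held, and Adgre1 and Cd163 passed as well. The MHC class II call ended without Adrb3-/- ICH replicate 2 (0.0522) or 3 (0.282), the macrophage list call without Adrb3-/- sham replicate 1 (0.164) or Adrb3-/- ICH replicate 2 (0.0522) or 3 (0.384). The neutrophil median was 0.24 without Adrb3-/- sham replicate 3.

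**Figure D2:**
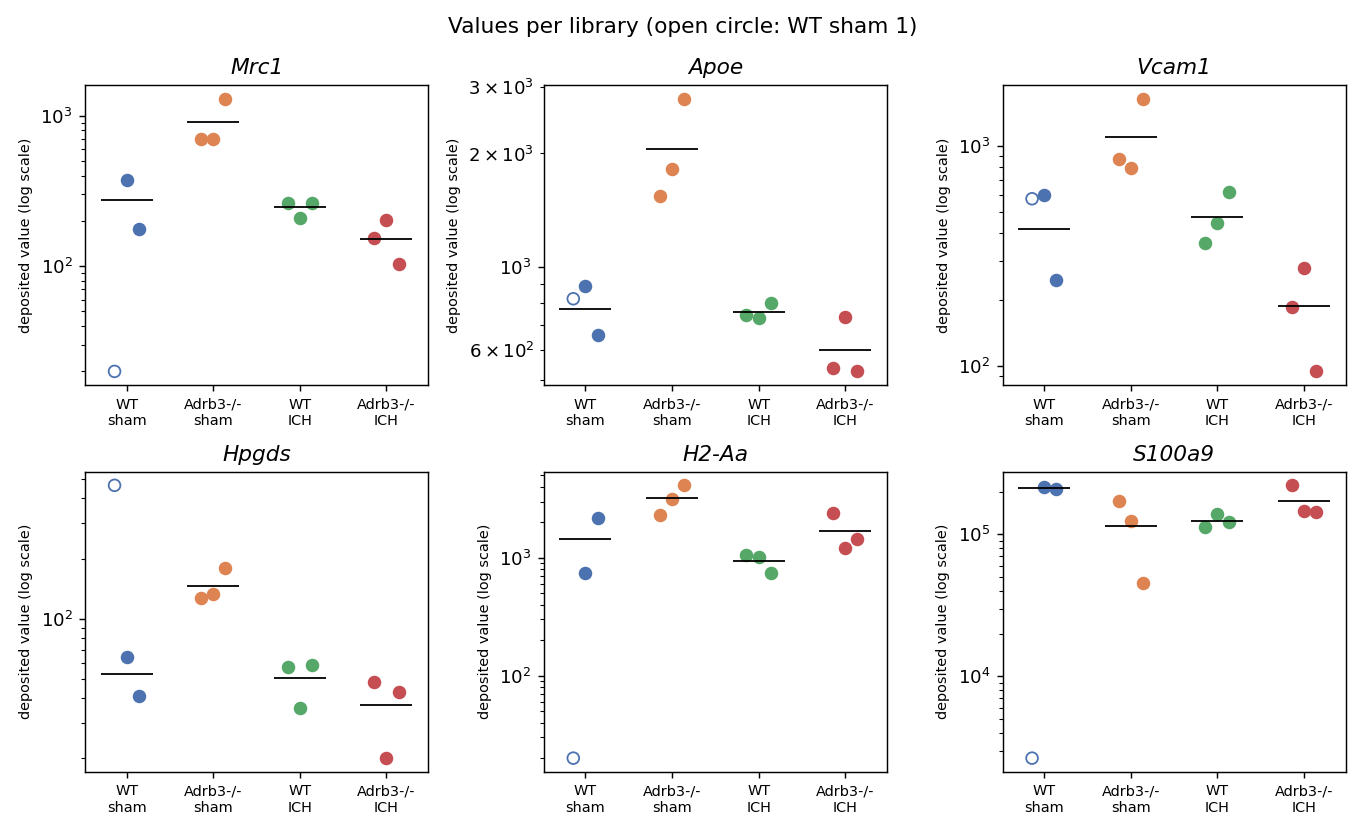
Deposited values of Mrc1, Apoe, Vcam1, Hpgds, H2-Aa and S100a9 in each library (log scale), by group, where filled points are the 11 libraries, bars their group means and the open circle wild-type sham replicate 1. Mrc1 averages 902 in Adrb3-/- sham libraries and 153 in Adrb3-/- ICH libraries, against 275 and 246 in the wild-type groups.

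The comparison of ICH with sham in wild-type mice asks how the sorted cells differed after ICH with the receptor present. NF-kB and inflammatory cytokine genes were lower after ICH as a group. With 11 libraries 23 of 24 members were negative, with a median log2 change of -0.31 (camera, adjusted p = 0.0195), and with 12 libraries 23 of 24 with a median of -0.81 (0.0237). Adjusted p was 0.967 and 0.941 with an estimated correlation, and none of the 24 passed on its own in either adjustment. Ptgs2, the inducible cyclooxygenase, averaged 287 ± 242 in sham (n = 2) and 89.4 ± 3.99 in ICH libraries (n = 3), a log2 change of -1.36 (SE 0.79), the chemokine gene Ccl3 stood at -1.02 (SE 0.64) and the NF-kB regulator gene Nfkbiz at -0.93 (SE 0.60). All 3 had an adjusted p of 1.

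No single gene passed in this comparison (limma), with 14 genes at an unadjusted p under 0.05 with 12 libraries and 2 with 11, and 1 gene passed without wild-type sham replicate 2. The 2 were Casp1, the inflammasome protease, at -0.48 (SE 0.21) and the metalloprotease gene Zmpste24 at -0.53 (SE 0.23). Acod1, which makes itaconate in activated macrophages, stood at -1.13 (SE 0.53), the nonclassical MHC class I gene H2-T23 at 0.52 (SE 0.25), and Irf8, a transcription factor of monocytes and dendritic cells, at 1.79 (SE 0.87), each with an adjusted p of 1. With 12 libraries Casp1 stood at -0.96, Zmpste24 at -0.93 and H2-T23 at 0.17. In the same fit Irf8 stood at 2.43, Acod1 at -1.64, Ptgs2 at -2.11, the lipopeptide receptor gene Tlr2 at -1.36 (-0.74 with 11) and the interferon-induced chemokine gene Cxcl10 at -1.54, each with an adjusted p of 0.484, against a median of all genes of -0.54 that was -0.11 without the failed library. Reference genes passed as a list with 12 libraries (10 of 19 positive, adjusted p = 0.00822, 0.111 with an estimated correlation) but not with 11 (0.488). The geometric mean of the 20 reference genes was 437 in each of the 11 libraries and 205 in the failed one. Their mean level was thus equal across the 11, and with 12 it is moved by the failed library. Neither outcome, here or in the comparisons below, is a result about these genes.

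The call for NF-kB and inflammatory cytokine genes rests on wild-type sham replicate 3, without which 11 libraries gave an adjusted p of 0.9 in the other direction, with Ccl3 at 0.03, Nfkbiz at 0.06 and Irf8 at -0.14, and it also ended without wild-type ICH replicate 1 (0.0879) or 2 (0.0597) or Adrb3-/- ICH replicate 1 (0.0699). In simulated data of this comparison with 11 libraries and 200 of 593 genes changed, 47.9% of genes changed by 1 on the log2 scale were recovered. Of those changed by 2, 91.0% were recovered. Draws with few changed genes, where the adjusted threshold is harder to pass, were not run. These shares therefore do not give the power of the real comparison.

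The comparison of Adrb3-/- with wild-type mice after sham surgery asks what the missing receptor did without ICH. MHC class II genes were higher in Adrb3-/- libraries, with 11 of 12 members positive and a median log2 change of 0.79 with 11 libraries (camera, adjusted p = 2.17e-08, 0.888 with an estimated correlation), and 9 of 12 with a median of 0.68 with 12 (3.24e-04 and 0.188). H2-Aa averaged 1459 ± 1008 in wild-type (n = 2) and 3207 ± 897 in Adrb3-/- libraries (n = 3), at 1.29 (SE 0.47; 3.27 with 12 libraries), with H2-Ab1 at 1.31 (SE 0.44) and H2-Eb1 at 1.14 (SE 0.40). Each had an adjusted p of 0.808. With 12 libraries 2 members passed when adjusted over the list alone and 0 over all genes, and with 11 libraries none in either way. MHC class I and antigen processing genes were higher in 13 of 14 members (median 0.25, adjusted p = 0.00549, 0.888 with an estimated correlation; 0.0188 and 0.188 with 12). Monocyte, macrophage and dendritic cell markers were higher as a list (adjusted p = 0.0297, 0.888 with an estimated correlation; 0.0313 and 0.503 with 12), with 10 of 18 members positive and a median of 0.25, and 1 passed when adjusted over the list alone with 11 libraries. Of its members, Mrc1 stood at 1.75 (SE 0.41, adjusted p = 0.549; 2.95 with 12 libraries), and Cd163 at 1.43 (SE 0.48) and the lysosomal glycoprotein gene Cd68 at 1.05 (SE 0.35), both with an adjusted p of 0.808. Outside the list, Apoe stood at 1.38 (SE 0.29, 0.498) and Hpgds at 1.47 (SE 0.40, 0.808), which was 0.42 with 12 libraries.

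Mature neutrophil markers were lower in Adrb3-/- sham libraries with 11 libraries, in 13 of 13 members with a median of -0.85 (adjusted p = 4.21e-05, 0.888 with an estimated correlation), but the list did not pass with 12 (0.806). Adrb3-/- sham replicate 3, with 23.2% of its counts in S100a8 and S100a9, stands in this group. S100a9 stood at -1.09 with 11 libraries and at 1.01 with 12, and Hdc, the histamine-forming enzyme, at -0.85 and -1.22. Leaving aside Adrb3-/- sham replicate 3 as well as the failed library, S100a9 stood at -0.53. Chemokine ligand genes passed with 12 libraries (21 of 21 negative, median -0.99, adjusted p = 0.0205, 0.893 with an estimated correlation) and not with 11 (0.178). The median change of all genes was -0.46 with 12 libraries and -0.10 with 11, so part of that -0.99 is shared by all genes. Their member Pf4, platelet factor 4, stood at -0.84 with 11 libraries, and Zmpste24 at -0.66 with 11 and -1.05 with 12. Reference genes also passed with 12 libraries alone (median 0.70, adjusted p = 0.0258, 0.188 with an estimated correlation; 0.523 with 11).

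No gene passed in the sham comparison (limma, smallest adjusted p = 0.438 with 12 libraries and 0.498 with 11), with 30 and 35 genes at an unadjusted p under 0.05. The 3 Adrb3-/- sham libraries also stand in the comparison of ICH with sham in Adrb3-/- mice, so the opposite directions of macrophage, MHC class II and neutrophil genes there are not independent. Without wild-type sham replicate 2, 1 gene passed, the MHC class I list ended without that library (0.501) or Adrb3-/- sham replicate 3 (0.147), and the macrophage list without wild-type sham replicate 3 (0.44), Adrb3-/- sham replicate 1 (0.217) or Adrb3-/- ICH replicate 1 (0.107). The call for monocyte, macrophage and dendritic cell markers also ended with median centring of the 12 (0.164) or 11 libraries (0.0508) and with quantile normalization of the 11 (0.233).

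The comparison of Adrb3-/- with wild-type mice after ICH asks what the missing receptor did with ICH. MHC class I and antigen processing genes were higher in Adrb3-/- libraries, with 13 of 14 members positive and a median log2 change of 0.33 (camera, adjusted p = 0.00169 with 11 libraries, 0.613 with an estimated correlation; 0.00557 and 0.240 with 12). Psmb8, an immunoproteasome subunit gene, averaged 728 ± 28.2 in wild-type and 1124 ± 58.6 in Adrb3-/- libraries (n = 3 each), at 0.63 (SE 0.19), and the peptide transporter gene Tap2 stood at 0.56 (SE 0.25). Prg2, the gene of the eosinophil major basic protein, averaged 3919 ± 2496 in wild-type and 866 ± 161 in Adrb3-/- libraries, at -2.01 (SE 0.60), and the related gene Prg3 stood at -1.47 (SE 0.48). Neither passed, wild-type ICH replicate 3 had the highest Prg2 value (6784), and without it the change of Prg2, Adrb3-/- vs wild type in ICH, was -1.53. The list of mast cell, basophil and eosinophil markers did not pass (adjusted p = 0.140 with 11 libraries and 0.0741 with 12). Arhgef6, a guanine nucleotide exchange factor gene, stood at 0.74 (SE 0.19), the leukotriene synthesis gene Alox5ap at 0.83 (SE 0.31) and the kinase gene Pik3cg at 0.63 (SE 0.21). Il6 stood at -1.55 (SE 0.50), Cxcr1 at -1.38 (SE 0.40), the granzyme gene Gzma at -1.58 (SE 0.46) and, by the rule with 12 libraries, Vcam1 at -1.45 (SE 0.52).

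No gene passed in the ICH comparison of the genotypes (limma, adjusted p = 0.513 for each of the genes named with 11 libraries and 1 with 12), with 9 genes at an unadjusted p under 0.05 with 12 libraries and 52 with 11. The call for MHC class I and antigen processing genes ended without Adrb3-/- ICH replicate 1 (0.072), with quantile normalization of the 11 libraries (0.0787) and with median centring of the 12 (0.0643), but not of the 11 (0.00426). Il6, Cxcr1 and Gzma each had counts under 20 in Adrb3-/- ICH replicate 2, where the level is only known to lie under 103, as had Gzma in Adrb3-/- ICH replicate 3 (under 43.0).

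The interaction of genotype and ICH asks whether the effect of ICH differed between the genotypes. Among the genes named by the rule, negative interaction values were found for Mrc1 at -2.47 (SE 0.55), Apoe at -1.73 (SE 0.39), Vcam1 at -2.89 (SE 0.72), Hpgds at -1.96 (SE 0.54; -0.91 with 12 libraries), Cd163 at -2.27 (SE 0.64) and Adgre1 at -1.69 (SE 0.48) with 11 libraries. Hpgds was under 20 counts in Adrb3-/- ICH replicate 2. With that value at its limit of 103, its change with ICH in Adrb3-/- mice, which enters the interaction, was -1.26 against -2.03. Ccr3, an eosinophil chemokine receptor gene, was also named on the negative side. Mapk13 stood at 1.51 (SE 0.48). No gene passed (limma, adjusted p = 0.389 for Mrc1 and Apoe with 11 libraries and 0.848 with 12), with 18 genes at an unadjusted p under 0.05 with 12 libraries and 25 with 11. The 4 genes that passed in Adrb3-/- mice were not shown to respond differently from wild type. As lists, monocyte, macrophage and dendritic cell markers passed as lower (adjusted p = 0.0224 with 11 libraries, 0.965 with an estimated correlation; 0.0110 and 0.765 with 12), with 11 of 18 members negative and a median of -0.49, of which 6 passed with 11 libraries when adjusted over the list alone and 0 over all genes. Mature neutrophil markers passed as higher with 11 libraries (13 of 13 positive, median 1.16, adjusted p = 3.87e-06, 0.965 with an estimated correlation) and not with 12 (0.354). S100a9 stood at 1.53 with 11 libraries and at -0.58 with 12, and Adrb3-/- sham replicate 3 had the low share of S100a8 and S100a9 given above. Leaving aside that library as well gave 0.959 for S100a9, and quantile normalization of the 11 libraries gave 0.122. Across the 593 genes the log2 changes with ICH in the 2 genotypes correlated at r = 0.0704 (rho 0.148) with 12 libraries and at r = -0.203 (rho -0.178) with 11, where genes are not independent replicates. Without wild-type sham replicate 2, 1 gene passed, and the macrophage list call ended without wild-type sham replicate 3 (0.135), Adrb3-/- sham replicate 1 (0.145), wild-type ICH replicate 2 (0.0789) or Adrb3-/- ICH replicate 3 (0.461), and with median centring of the 12 libraries (0.102).

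**Figure D3:**
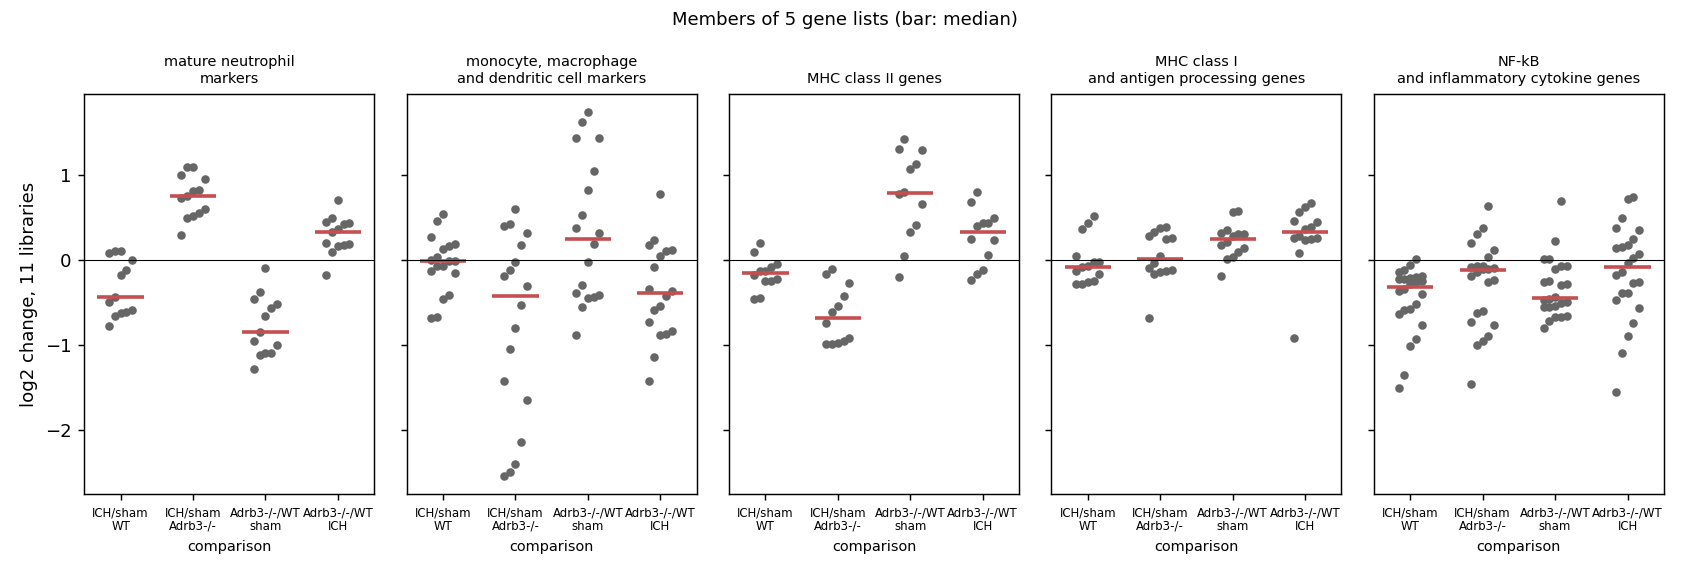
Log2 change (vertical axis, 11 libraries) of the members of 5 gene lists in 4 comparisons, with 1 point per gene and a bar at the median. The median of mature neutrophil markers stands at 0.75 for ICH against sham in Adrb3-/- mice and at -0.85 for Adrb3-/- against wild type after sham surgery.

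Averaged over the genotypes, ICH libraries had lower MHC class II genes with 11 libraries, in 12 of 12 members with a median log2 change of -0.42 (camera, adjusted p = 0.00199, 0.799 with an estimated correlation). Monocyte, macrophage and dendritic cell markers were also lower, in 14 of 18 with a median of -0.32 (0.0321 and 0.799). Neither list passed with 12 libraries (0.409 and 0.454). Mature neutrophil markers were higher in both fits (10 of 13 positive, median 0.16, adjusted p = 1.12e-04 with 11 libraries, 0.799 with an estimated correlation; 11 of 13, median 0.48, 7.91e-06 and 0.285 with 12). With 11 libraries this list passed as higher for ICH in Adrb3-/- mice (median 0.75) and not in wild type. The change of every member was lower in wild type than in Adrb3-/- mice. The average is thus not a rise shown in both genotypes. With 12 libraries NF-kB genes were lower (0.0334, 0.890 with an estimated correlation), and MHC class I genes (0.0334 and 0.270) and reference genes (0.00186 and 0.0816) higher, none of which passed with 11 (0.0736 for each). Mrc1 stood at -1.31 (SE 0.28), Apoe at -0.88 (SE 0.19), Hpgds at -1.04 (SE 0.27), Adgre1 at -0.81 (SE 0.24), Cd86 at -0.50 (SE 0.15) and H2-T23 at 0.39 (SE 0.17) with 11 libraries. With 12, Mrc1 stood at -0.70, Hpgds at -1.57, Cd86 at -0.83 and H2-T23 at 0.21. The Hpgds average includes a value under 20 counts in Adrb3-/- ICH replicate 2. At its limit of 103 the Adrb3-/- part of that average was -1.26 against -2.03 with 11 libraries. No gene passed (limma, smallest adjusted p = 0.647 with 12 libraries and 0.348 with 11), with 19 and 28 genes at an unadjusted p under 0.05. With 11 libraries as the start, the neutrophil call ended without Adrb3-/- sham replicate 3 (0.154) or Adrb3-/- ICH replicate 1 (0.111). The MHC class II call ended without wild-type sham replicate 3 (0.235) or Adrb3-/- ICH replicate 2 (0.0544) or 3 (0.188), and the macrophage call ended without any of wild-type sham replicate 2 (0.254), wild-type ICH replicate 1 (0.112), Adrb3-/- sham replicate 1 (0.109) and Adrb3-/- ICH replicates 2 (0.0544) and 3 (0.454).

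Averaged over the treatments, Adrb3-/- libraries had higher MHC class II genes, in 11 of 12 members with a median log2 change of 0.57 (camera, adjusted p = 4.06e-07 with 11 libraries, 0.482 with an estimated correlation; 7.84e-05 and 0.139 with 12). MHC class I and antigen processing genes were also higher, in 13 of 14 with a median of 0.25 (8.06e-06 and 0.482; 1.57e-04 and 0.0972 with 12). H2-Aa stood at 1.04 (SE 0.31; 2.03 with 12 libraries), H2-Ab1 at 0.90 (SE 0.29), H2-DMb2, of the chaperone that exchanges peptides on class II molecules, at 0.87 (SE 0.27) and Psmb8 at 0.40 (SE 0.14), and 3 of the class II members passed when adjusted over the list alone and 0 over all genes. Chemokine ligand genes were lower, in 18 of 21 members with a median of -0.34 (0.0378, 0.482 with an estimated correlation; 0.00611 and 0.964 with 12), with Pf4 at -0.63 (SE 0.20). Prg3 stood at -1.21 (SE 0.36) and Cxcr1 at -0.93 (SE 0.30; -1.43 with 12 libraries). Reference genes passed with 12 libraries alone (0.0212, 0.139 with an estimated correlation; 0.289 with 11). No gene passed (limma, smallest adjusted p = 0.613 with 12 libraries and 0.654 with 11), with 29 and 36 genes at an unadjusted p under 0.05. The call for chemokine ligand genes ended without wild-type sham replicate 3 (0.0665), wild-type ICH replicate 1 (0.0749) or Adrb3-/- ICH replicate 1 (0.125) or 3 (0.0613). It also ended with quantile normalization of the 11 libraries (0.117), the filter recomputed on them (0.079), every value raised to at least 103 (0.0614) or values at 20 set to the worth of 20 counts in their library (0.051).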

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

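The tests of explanations for the genes lower after ICH, neutrophil genes and wild-type sham replicate 1 were chosen after the results were seen, and those of other splits of the libraries before. In the interaction of genotype and ICH, 2 lists passed the test with a preset correlation: monocyte, macrophage and dendritic cell markers (camera, adjusted p = 0.0110 with 12 libraries and 0.0224 with 11) and mature neutrophil markers with 11 libraries (3.87e-06). With an estimated correlation adjusted p was 0.765, 0.965 and 0.965, and neutrophil markers did not pass with 12 libraries (0.354). With 12 libraries 87 of 100 drawn splits gave at least the real 1 list, so chance was not excluded and a difference between the genotypes was not shown.

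In Adrb3-/- mice 12 genes had an adjusted p under 0.10 for ICH against sham with 11 libraries, all 12 negative, of which 6 are in the fixed list of monocyte, macrophage and dendritic cell markers and 4 in no fixed list. Hpgds and Igf1 had a value at 20 in Adrb3-/- ICH replicate 2, and with it at its limit of 103 their median went from -1.99 to -1.22 (larger SE 0.35), which argues against the deposited value for low counts as the whole source and leaves part of the size open, while the other 10 held no such value. Without Adrb3-/- sham replicate 3 the median of the 12 was -1.87 (range -2.39 to -1.15), against -2.09 with it, so all 12 stayed lower after ICH. The 12 had been chosen in a fit that held this library, which favours genes alike across its group. Their median therefore cannot decide how far the calls rest on it. No gene passed without Adrb3-/- sham replicate 3, where the changes were smaller (Mrc1 -2.25 against -2.54, Apoe -1.50 against -1.74) in a fit with fewer libraries. Within groups the 12 went up and down together (mean correlation of residuals 0.617, against 0.187 at the 95th percentile of random gene sets), as a varying share of RNA of another cell type may give and as joint regulation may give too. The 18 tested markers of the fixed list did so less (0.224, against 0.148 at the 95th percentile), which leaves macrophage RNA undecided. Of these 18, 9 are in another fixed list, means ran from 61.6 to 1819, and a sort gate for HSCs would be meant to remove macrophages. An effect of ICH on cells lacking the receptor stays open and was not tested apart from these.

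Mature neutrophil genes were higher in Adrb3-/- ICH than in Adrb3-/- sham libraries. Without Adrb3-/- sham replicate 3 the median of the 13 members went from 0.75 to 0.24 (range 0.03 to 0.66), so that library, with 23.2% of its counts in S100a8 and S100a9, may account for most of the size. Without Adrb3-/- ICH replicate 1, where POS_A gave 6278 counts, the median was 0.49 (range -0.31 to 0.70), which leaves a part of that library undecided. Members went up and down together within groups (mean correlation of residuals 0.755, against 0.175 at the 95th percentile of random gene sets), as a varying share of neutrophil RNA would give and as joint regulation would give too. Of the 13, 4 are in another fixed list, means ran from 211 to 150064 (S100a9), and a sort gate for HSCs would be meant to remove mature neutrophils. Their RNA was nonetheless abundant: all 13 had at least 20 counts in each of the 11 libraries. Camp averaged 28692 and Mmp8 853, against 167 for Kit. Which cells this RNA came from was not tested. A biological difference stays open and untested.

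Wild-type sham replicate 1 was unlike the other libraries. POS_A, a control added independently of the sample, gave 79 counts there and at least 6278 elsewhere, which argues against a low amount of sample RNA alone and is consistent with a reaction or readout that failed as a whole. No biological explanation was tested.

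Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. For ICH against sham in wild type the real split gave 14 genes at an unadjusted p under 0.05 (3 splits gave as many, highest other 89) and 2 lists (4 splits, highest other 4). All 10 splits include the failed library, and which libraries the split with 89 genes put together was not examined. In Adrb3-/- mice it gave 22 genes (1 split, highest other 13) and 3 lists, a number that all 10 splits reached (highest other 5), and with 11 libraries 4 genes past the threshold (1 split, highest other 0) and 3 lists (6 splits, highest other 4). Adrb3-/- against wild type gave 30 genes (3 splits, highest other 39) and 5 lists (1 split, highest other 4) after sham surgery, and 9 genes (2 splits, highest other 10) and 1 list (9 splits, highest other 5) after ICH. For the interaction 21 of 100 drawn splits gave at least the real 18 genes and 87 at least the real 1 list (highest others 64 and 7). For ICH averaged over genotypes 16 gave at least 19 genes and 14 at least 4 lists (highest others 44 and 7). For Adrb3-/- averaged over treatments 11 gave at least 29 genes and 26 at least 4 lists (highest others 47 and 7). Chance was not excluded for any of these 6 counts.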

How the results depend on the processing

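Settings that start from 11 libraries and leave aside a further one, the common floor, the worth of 20 counts in its library for each value at 20 (own limit) and the recomputed filter were chosen after the data were seen. The 68 printed pairs of gene and comparison gave 2688 values under the alternatives, of which 2576 kept their direction and side of the threshold, 66 passed it and 46 turned (7 pairs). They were set against the fit with 12 libraries, where no gene passed. A kept side therefore only means not passing, and says nothing on how stable the size of a change was. The 20 list calls with 12 libraries gave 720 values: 457 the same, 261 past the threshold no longer and 2 turned. Low counts limit genes near a value of 103, the worth of 20 counts in Adrb3-/- ICH replicate 2. Count models were not run, since the deposited values are not counts. Where no construction is named, the cause was not tested.

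Against 0 genes past the threshold with 12 libraries, an unadjusted p under 0.05 gave, with 12 and 11 libraries, 14 and 2 for ICH in wild type, 22 and 48 for ICH in Adrb3-/-, 30 and 35 for Adrb3-/- in sham, 9 and 52 for Adrb3-/- in ICH, 18 and 25 for the interaction, 19 and 28 for ICH averaged and 29 and 36 for Adrb3-/- averaged. Array weights gave 5 for Adrb3-/- in sham and 11 for ICH in Adrb3-/-. For ICH in Adrb3-/- a stricter filter gave 1, a trend with robust prior 2 and, with 11 libraries, the common floor or own limit 5, the recomputed filter 7, median centring 2, quantile normalization 2 and an adjusted p under 0.10 12. Leaving aside also 1 library gave 16 (Adrb3-/- ICH 1), 3 (Adrb3-/- ICH 2), 2 (Adrb3-/- sham 1, wild-type ICH 1 or 3) and 6 (wild-type sham 2 or 3). Leaving aside wild-type sham 2 gave 1 each for Adrb3-/- in sham, ICH in wild type and the interaction. Leaving out 1 of 12 libraries gave 0 to 4 for ICH in Adrb3-/- and 0 to 1 for Adrb3-/- in sham, ICH in wild type and the interaction.

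The correlation of ICH effects between genotypes, 0.0704 with 12 libraries, ranged from -0.203 to 0.135 without 1 library and was -0.0208 with no filter. With 11 libraries it was -0.178 with the common floor, -0.158 with the own limit, -0.243 with the recomputed filter, -0.203 with median centring and -0.157 with quantile normalization. Median centring shifts all changes of a comparison equally, so it could not move this correlation. Leaving aside also Adrb3-/- ICH 1, 2 or 3 it was -0.231, -0.114 and -0.184, Adrb3-/- sham 1, 2 or 3 -0.284, -0.218 and -0.0654, wild-type ICH 1, 2 or 3 -0.112, -0.282 and -0.171, and wild-type sham 2 -0.268.

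All list calls made with a preset correlation ended with an estimated correlation, and with fry's test of a shift to one side, in every comparison with 12 and 11 libraries. The first left 0 lists, and the second 0 except 1 list that had not been called, cell cycle genes for Adrb3-/- averaged with 11 libraries. Fry's test of change in either direction gave 3 lists for ICH in Adrb3-/- with 11 libraries, among them the monocyte, macrophage and dendritic cell markers, and 0 in the other 13 cases. For Adrb3-/- averaged (4 lists) the common floor, quantile normalization of 11 libraries and leaving aside Adrb3-/- ICH 3 or wild-type ICH 1 gave 2. For Adrb3-/- in ICH (1 list) median centring of 12 and quantile normalization of 11 libraries gave 0, the common floor and centring on reference genes 2, the recomputed filter 3, leaving aside Adrb3-/- ICH 2 gave 4 and Adrb3-/- ICH 1 or 3, Adrb3-/- sham 3 or wild-type ICH 2 gave 2. For Adrb3-/- in sham (5 lists) median centring and quantile normalization of 11 libraries and leaving aside Adrb3-/- sham 1 or 3 gave 3. For ICH averaged (4 lists) leaving aside Adrb3-/- ICH 2 or Adrb3-/- sham 1 gave 2 and Adrb3-/- ICH 3 gave 1, and for ICH in Adrb3-/- (3 lists) Adrb3-/- ICH 2 or 3 gave 1. For ICH in wild type (2 lists) the common floor, the own limit, the recomputed filter, median centring and quantile normalization of 11 libraries gave 1, and median centring of 12 gave 4. Leaving aside wild-type sham 3 gave 4, Adrb3-/- ICH 1 or wild-type ICH 1 or 2 gave 0, and Adrb3-/- ICH 2 or 3, any Adrb3-/- sham library or wild-type ICH 3 gave 1. For the interaction (1 list) the common floor, the own limit and quantile normalization of 11 libraries gave 3, the recomputed filter 2, median centring 2 with 11 libraries and 0 with 12. Leaving aside Adrb3-/- ICH 1 or wild-type ICH 3 gave 3, and Adrb3-/- ICH 2, any Adrb3-/- sham library, wild-type ICH 1 or wild-type sham 2 or 3 gave 2. Leaving out 1 of 12 libraries gave 1 to 5 lists for Adrb3-/- in ICH (2 to 5 where the number moved), 3 to 5 in sham, 2 to 6 for ICH averaged, 1 to 5 for ICH in Adrb3-/-, 1 to 2 for ICH in wild type and 0 to 4 for the interaction.

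Among genes, S100a9 turned most. S100a9 had at least 20 counts in all 11 libraries, so the own limit could not move its changes. The change of S100a9, Adrb3-/- vs wild type in sham, was -1.09 with 11 libraries, -0.745 with array weights and -1.05 with median centring of 11. Leaving aside Adrb3-/- sham 1, 2 or 3 it was -1.496, -1.26 and -0.53, and wild-type sham 2 or 3 -1.06 and -1.13. It ranged from -1.09 to 2.08 without 1 library. That of S100a9, interaction of genotype and ICH, was 1.53 with 11 libraries, 1.52 with median centring of 11, 1.004 with array weights, and 0.122 and 0.120 with quantile normalization of 11 and 12. Leaving aside Adrb3-/- ICH 1, 2 or 3 it was 1.32, 1.62 and 1.63, Adrb3-/- sham 1, 2 or 3 1.93, 1.69 and 0.959, wild-type ICH 1, 2 or 3 1.46, 1.608 and 1.51, and wild-type sham 2 or 3 1.495 and 1.56. It ranged from -1.65 to 1.53 without 1 library. The change of Ccl3, ICH vs sham in wild type, was 0.0299 leaving aside wild-type sham 3 and 0.0552 with quantile normalization (-1.04 to 0.00667 without 1 library). That of H2-T23, ICH vs sham in wild type, was -0.18 with centring on reference genes (-0.0331 to 0.52). In the same comparison Irf8 was -0.14 and Nfkbiz 0.0556 leaving aside wild-type sham 3. Hpgds for Adrb3-/- in sham ranged from -0.27 to 1.47.

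The replicate number did not pair the libraries: residuals of the 15 pairs with the same number correlated at a median of -0.158 (-0.403 to 0.177, 2 over 0.1), against 0.0812 for the other 30. With the replicate number as a block, ICH in wild type gave 1 list with 12 libraries and 0 with 11, the correlation of ICH effects was -0.230 with 11, and S100a9 was -1.27 for Adrb3-/- in sham and 1.71 for the interaction with 11.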

Other observations

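Eosinophil granule genes, chosen after their values were seen, differed widely between wild-type libraries of the same group. Epx, the eosinophil peroxidase gene, reached 607 in wild-type sham replicate 2 and 673 in wild-type ICH replicate 3, stood between 92.9 and 213 in the other 3 working wild-type libraries, and between 76.8 and 138 in the 6 Adrb3-/- libraries. Prg2 was highest in the same 2 libraries, at 5718 and 6784. Mast cell, basophil and eosinophil markers passed as a list in no comparison, with a smallest adjusted p (camera) of 0.0741 with 12 libraries and 0.140 with 11, both for Adrb3-/- against wild type after ICH.

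Of the 25 tested lists, 18 passed by camera with a preset correlation in no comparison with 12 or 11 libraries. With 11 libraries 3 of them passed by fry, cell cycle genes for a shift to one side (adjusted p = 0.0377, Adrb3-/- averaged) and chemokine receptor genes (0.00801) and complement and Fc receptor genes (0.0391) for change in either direction (ICH in Adrb3-/-). Stem and early progenitor genes came nearest among those on stem cells, for Adrb3-/- against wild type averaged over treatments (5 of 5 tested members positive, median log2 change 0.61, adjusted p = 0.0759 with 11 libraries and 0.0647 with 12). The fixed list is longer. Of the 5 tested genes, 3 are in another fixed list and 3 had at least 20 counts in all 11 libraries. Tested members of the list included Cd34, which ranged from 266 to 1880 over the 11 libraries, and Kit, which was under 20 counts in Adrb3-/- ICH replicate 1 and reached 293 in Adrb3-/- ICH replicate 3. With 11 libraries the smallest adjusted p (camera) over the 7 comparisons was 0.510 for myeloid commitment and granule genes, 0.407 for lymphoid commitment genes, 0.412 for type I interferon response genes, 0.608 for Toll-like receptor and inflammasome genes, 0.140 for chemokine receptor genes, 0.0935 for cytokine receptor and Jak-Stat genes and 0.222 for cell cycle genes. It was 0.297 for apoptosis genes, 0.649 for immediate early and sorting stress genes, 0.25 for Ras and MAP kinase genes, 0.423 for Wnt genes, 0.734 for TGF-beta and BMP genes, 0.580 for complement and Fc receptor genes, 0.690 for metabolic genes, 0.621 for T cell markers and 0.127 for stromal and endothelial cell markers. These values rest on the tested members alone, from 5 (Wnt genes, T cell markers) to 19 (Toll-like receptor and inflammasome genes) per list.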
